A study of Homo sapiens with 9 samples.

How the data were processed

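The samples were 9 libraries of total RNA from cells labelled HepG2, with 3 lentiviral constructs (lvNC, lvN3 and lvN3D) at days 0, 3 and 6 and 1 library per construct and day. The group of a library was its construct, taken from the labels, and replicates 1, 2 and 3 of a construct are days 0, 3 and 6. RNA was extracted with TRIzol, per the labels' protocols. The authors aligned the reads to GRCh38 with HISAT2 (its version is not given in the sources used here) and counted them per gene with HTSeq 0.11.2, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and an antisense partner cannot be told apart. The deposited table gave whole-number counts per gene, not normalized, and FPKM values for each library, and the columns were matched to libraries by their names. The deposited FPKM equalled the count divided by the gene's length and the library's total, with a largest relative deviation of 9.55e-15 over 8339 genes checked. The table had 32600 genes, 0 lines that named no gene and 28 symbols used more than once. Gene positions were looked up by identifier in GENCODE release 29 on GRCh38, where all 32600 identifiers were found.

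Library totals were 14017031 to 16077949 counts, 22817 to 24695 genes had a read in a library, and TMM factors were 0.936 to 1.04. A gene with 0 counts in a group was given a floor of 3 counts over the group in fold bounds, ratios of low counts have exact 95% intervals, and both cover counting error only. Libraries were compared in pairs by a chi-square over genes with at least 20 summed counts.

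Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr (minimum count 10, construct as group) kept 16001 genes, TMM scaled the libraries, and the quasi-likelihood F test was fitted over all 9 libraries with construct and day as factors. That fit leaves 4 residual degrees of freedom, and its spread is that of the construct difference across days. The comparisons were lvN3 and lvN3D each with lvNC, lvN3 with lvN3D, the days with each other, F tests over the 3 constructs and over the 3 days, and the difference in slope per day between constructs (day as a number, 3 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. The biological coefficient of variation was 5.33% and the prior degrees of freedom were 23.3, or 26.5 for slopes.

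Named genes followed a rule fixed before the data were examined, as were the design, the alternatives and the gene lists. The rule named NFE2L3 and genes of the pathways in the series title, such as TRIM25, ISG15, CDKN1A and MDM2, in every comparison of constructs. For each comparison of 2 constructs and for day 6 against day 0, it named the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1, the same sign at all 3 days (or in all 3 constructs) and a symbol, and where fewer than 5 passed the 5 smallest p. It added up to 4 members with the smallest p from each list described. Some genes that the rule names are not reported here; counts and list tests include them. Genes whose spread or counts bear on a call, slope genes and genes drawn as markers were chosen after their values were seen.

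The 20 lists were p53 target genes, interferon-stimulated genes and ISG15 conjugation, proteasome subunits, DNA replication and G1/S genes, mitosis and G2/M genes, hepatocyte genes, NFE2L2 antioxidant targets, the CNC-bZIP family and partners, the unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis and storage, hypoxia and glycolysis, inflammatory and acute phase genes, epithelial-mesenchymal and matrix genes, heat shock genes, ribosomal protein genes, mitochondrially encoded genes, respiratory chain genes, markers of stromal, endothelial and blood cells, and cholangiocyte and progenitor markers. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted by Benjamini-Hochberg over the 20 lists of a comparison. Camera sets a list against the other genes, and fry tests whether a list's genes move one way.

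The alternatives were DESeq2 size factors, no filter, DESeq2 1.42.0, limma on log2(FPKM + 1) of genes with an FPKM of at least 1 in 3 libraries, a pseudocount of 0.1, no FPKM filter, leaving out each library in turn, leaving out the other factor, using only the 6 libraries compared, and day as a number. Scaling by column totals without TMM, slopes without each library and the alternatives of the overlap of responses were added after seeing the data. Overlap with shared controls was set beside 20 simulations. In these all 9 libraries, the controls included, were drawn without a construct difference, and both comparisons shared the simulated controls.

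The tests were tried on simulated counts for the 16001 genes with 200 genes changed by known folds. For lvN3 against lvNC edgeR recovered 26%, 66%, 82% and 96% of genes changed 1.25-, 1.5-, 2- and 4-fold, with 6 false calls among 141. DESeq2 recovered 24%, 64%, 76% and 92% with 1 false call among 129, and limma on FPKM 18%, 56%, 72% and 90% with 10 among 128. For day 6 against day 0 edgeR recovered 54%, 74%, 76% and 94% with 16 false calls among 165, and for slopes 2%, 20%, 60% and 76% with 6 among 85. Camera called the 1 changed list and none of 19 unchanged lists. The genes were simulated independently, so this does not show how camera behaves where the genes of a list are correlated. As only 200 of the 16001 genes were changed, as many up as down, the trial does not speak for lvN3 against lvNC. In that comparison most genes were called, and the split into higher and lower depended on the scaling. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.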

Results

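RNA was sequenced from human cells labelled HepG2, a line established from a liver carcinoma, after infection with 1 of 3 lentiviral constructs. The lvNC construct was the control, lvN3 carried NFE2L3, and lvN3D carried NFE2L3 without a part of its C-terminal region. NFE2L3 is a transcription factor of the CNC-bZIP family, to which NFE2L1 and NFE2L2 also belong. Infected cells were identified by green fluorescence and selected with puromycin, and the series title concerns NFE2L3, the proteasome, TRIM25 and p53 modified with ISG15. Each construct was sampled at days 0, 3 and 6 of a proliferation course, which gave 9 libraries with 1 library per construct and day. The library totals at days 0, 3 and 6 were 14017031, 16038638 and 14287735 counts for lvNC, 15592549, 15918843 and 16077949 for lvN3, and 15319174, 14737296 and 14804521 for lvN3D. At these totals 3 counts in 1 library corresponded to 0.187 to 0.214 CPM, the counts scaled to a common library total. The floor used in fold bounds for a gene at 0 was 3 counts over the 3 libraries of a group. The days are not replicates of a condition, and the labels do not say that cultures were separate, so the p-values measure only the spread between these samples. The ± values are standard deviations (SD) over the 3 libraries of a construct where they follow CPM, and standard errors (SE) where they follow log2 fold changes. Adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16001 genes unless another test is named.

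The libraries separated by construct. The first principal component held 73.8% of the variance and set lvN3 apart from lvNC and lvN3D, and the second held 5.89%. Correlations of log2 CPM across genes, which are not independent replicates, were 0.990 to 0.991 within a construct and 0.942 to 0.989 between constructs. No pair of libraries matched within sampling noise, since the mean chi-square per gene was 2.72 to 5.57 within a construct, where sampling alone gives 1, and 6.91 to 107 between constructs. Mitochondrially encoded genes took 2.73% to 3.61% of the counts, and the 10 most abundant genes of a library took 4.52% to 5.27%.

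**Figure D1:**
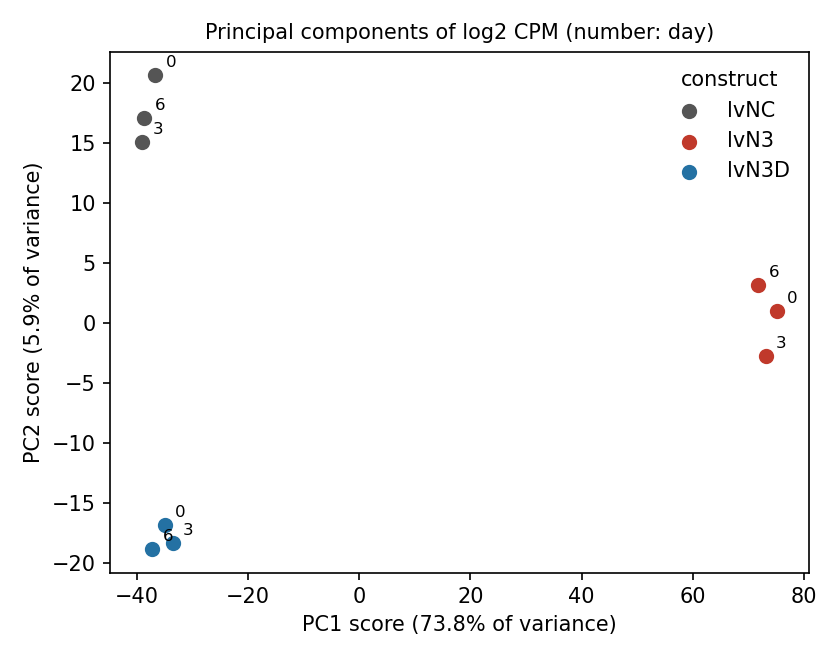
Principal components of log2 CPM for the 9 libraries, with PC1 on the x axis (73.8% of the variance), PC2 on the y axis (5.89%), colours for constructs and numbers for days. The lvN3 libraries lie apart from lvNC and lvN3D along PC1.

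Most genes characteristic of hepatocytes were close to the counting floor in all 9 libraries, whatever the construct. Of the 40 hepatocyte genes listed before the data were examined, 33 were found under the listed names, 26 of these were under 1 CPM in every library and 7 were abundant enough to be tested. Averaged over the 9 libraries, the mean CPM was 0.0357 for the apolipoprotein gene APOA1, 0.0506 for APOB, 0.0533 for the fetal liver gene AFP and 0.427 for the transcription factor HNF4A. CPS1, the first enzyme of the urea cycle, reached 2264 CPM. Among markers of other epithelial and mesenchymal cells, the keratin gene KRT7 was at 1299.9 CPM, the intermediate filament gene VIM at 221 CPM and the collagen gene COL1A1 at 154 CPM. Other stromal markers were low, with COL1A2 at 0.0439, PDGFRA at 0.0292, LUM at 0.547, COL3A1 at 6.09 and PDGFRB at 7.51 CPM. In contrast to KRT7, KRT19 was at 0.00751 CPM, EPCAM at 0.0156 CPM and the cadherin gene CDH1 at 0.227 CPM. ALB, TTR, APOH, AHSG, FABP1, RBP4 and GPC3 were looked up and were not among the 32600 genes with counts under those names. Of the 32600 genes, 0 were without a read in every library. Genes without reads may thus have been left out, and these genes have no value here. The housekeeping genes GAPDH and EEF1A1 were at 1435 and 6697 CPM. The libraries are therefore called by their construct, and HepG2 is given as the label.

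**Figure D2:**
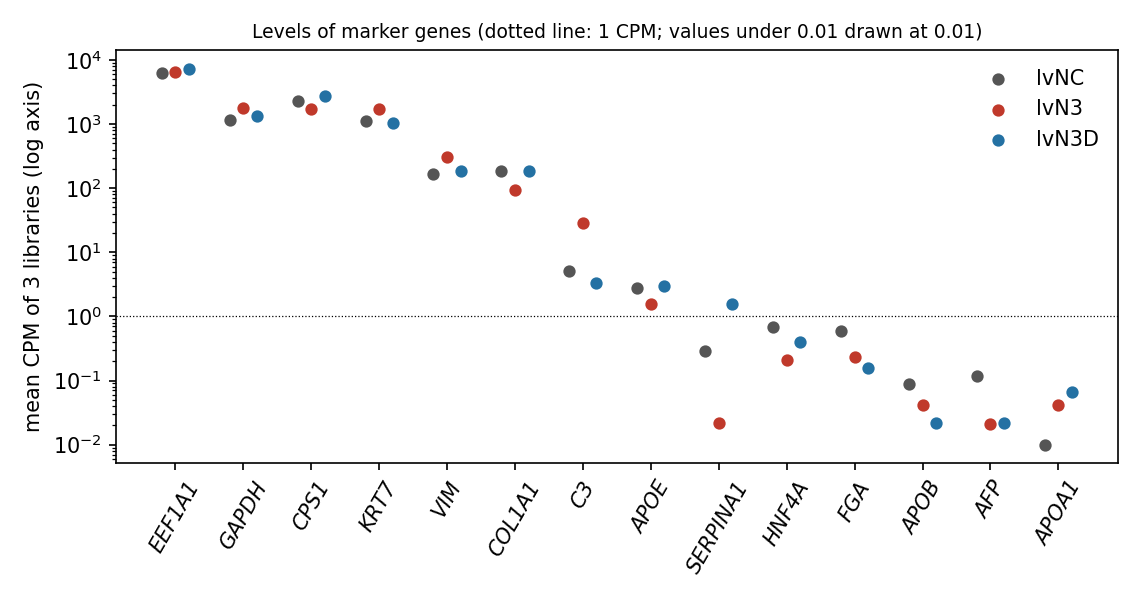
Mean CPM of 3 libraries (y axis, log scale, library totals without further scaling) for marker genes in lvNC, lvN3 and lvN3D, with values under 0.01 drawn at 0.01 and a dotted line at 1 CPM; the genes drawn were chosen after their values were seen. APOA1, APOB, AFP and HNF4A lie under 1 CPM, and CPS1, KRT7, VIM, COL1A1 and GAPDH lie above 100.

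Transcripts of genes listed as blood-cell markers stood out in 1 library, lvN3D at day 3. The leukocyte gene PTPRC had 143 counts there and 4 in the other 8 libraries together, and the T cell gene CD3E had 23 and 1. The B cell gene MS4A1 had 17 and 0, the lysozyme gene LYZ had 52 and 2, and the haemoglobin gene HBB had 133 and 1. In all, 49 genes had at least 15 counts in this library and at least 10 times the sum of the other 8. They held 2666 counts or 0.0181% of the library, and none of the other libraries had such a gene. None of the 49 was tested, since the filter asks for enough counts in as many libraries as a construct has. Genes confined to 1 library fail it whatever their count there. Without this library, lvN3D against lvNC had 867 calls in place of 1261, and 781 of them were shared.

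NFE2L3 (ENSG00000050344, chromosome 7, 26152240 to 26187125, plus strand, GRCh38) was far above the control in every library of both NFE2L3 constructs. In CPM at days 0, 3 and 6 it was at 9.34, 10.2 and 9.10 in lvNC, 502, 515 and 538 in lvN3, and 755, 802 and 854 in lvN3D. The deposited counts were 134, 169 and 135, then 7317, 7760 and 8135, then 11830, 12120 and 12946. These counts do not separate the cells' own transcript from that of the vector. The rise was 54.2-fold in lvN3 (log2 fold change 5.76 ± 0.07, adjusted p = 1.03e-30) and 84.0-fold in lvN3D (6.39 ± 0.07, adjusted p = 6.92e-32), and lvN3 was 1.55-fold lower than lvN3D (-0.63 ± 0.05, adjusted p = 1.34e-12).

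Other genes of the pathways the series title names were followed in all 3 constructs. TRIM25 (ENSG00000121060, chromosome 17, 56836387 to 56914080, minus strand), a ubiquitin and ISG15 ligase, was at 242 ± 33.8 CPM in lvNC, 408 ± 63.2 in lvN3 and 291 ± 11.6 in lvN3D (SD, n = 3). It rose in lvN3 (0.75 ± 0.06, adjusted p = 1.85e-11) and by less in lvN3D (0.28 ± 0.06, adjusted p = 0.00444), and was higher in lvN3 than in lvN3D (0.47 ± 0.06, adjusted p = 1.29e-07). The lvN3D call was lost with DESeq2 (adjusted p = 0.133) and with limma on FPKM (0.123), and without lvNC day 3 (0.0529) or lvN3D day 6 (0.108). ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014540, plus strand), the interferon-induced ubiquitin-like modifier, was at 30.2 ± 3.09 CPM in lvNC and 1105 ± 341 in lvN3, a 35.8-fold rise (5.16 ± 0.10, adjusted p = 4.75e-26). In lvN3D it was at 24.9 ± 0.589 CPM and did not pass the test (-0.28 ± 0.11, adjusted p = 0.125), although it did without lvNC day 0 (0.0435), lvN3 day 0 (0.0196) or lvN3D day 6 (0.0465). It was higher in lvN3 than in lvN3D (5.44 ± 0.10, adjusted p = 3.55e-26).

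CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), the p53-induced inhibitor of cyclin-dependent kinases, rose from 140 ± 8.95 to 224 ± 27.7 CPM in lvN3 (0.68 ± 0.06, adjusted p = 2.89e-10). In lvN3D it was at 157 ± 9.40 CPM (0.17 ± 0.06, adjusted p = 0.116), past the threshold only without lvNC day 0 (0.0130), and lvN3 was higher than lvN3D (0.51 ± 0.06, adjusted p = 5.27e-08). MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686, plus strand), the ubiquitin ligase of p53, rose from 65.3 ± 3.05 to 84.4 ± 2.75 CPM in lvN3 (0.37 ± 0.06, adjusted p = 1.02e-05). In lvN3D it was at 74.8 ± 4.90 CPM (0.19 ± 0.06, adjusted p = 0.0581), past the threshold without lvNC day 3 (0.0439) or lvN3D day 3 (0.0469). It was higher in lvN3 than in lvN3D (0.18 ± 0.06, adjusted p = 0.016), a call lost without lvN3 day 6 (0.108) or lvN3D day 3 (0.156) and with limma on FPKM (0.533).

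**Figure D3:**
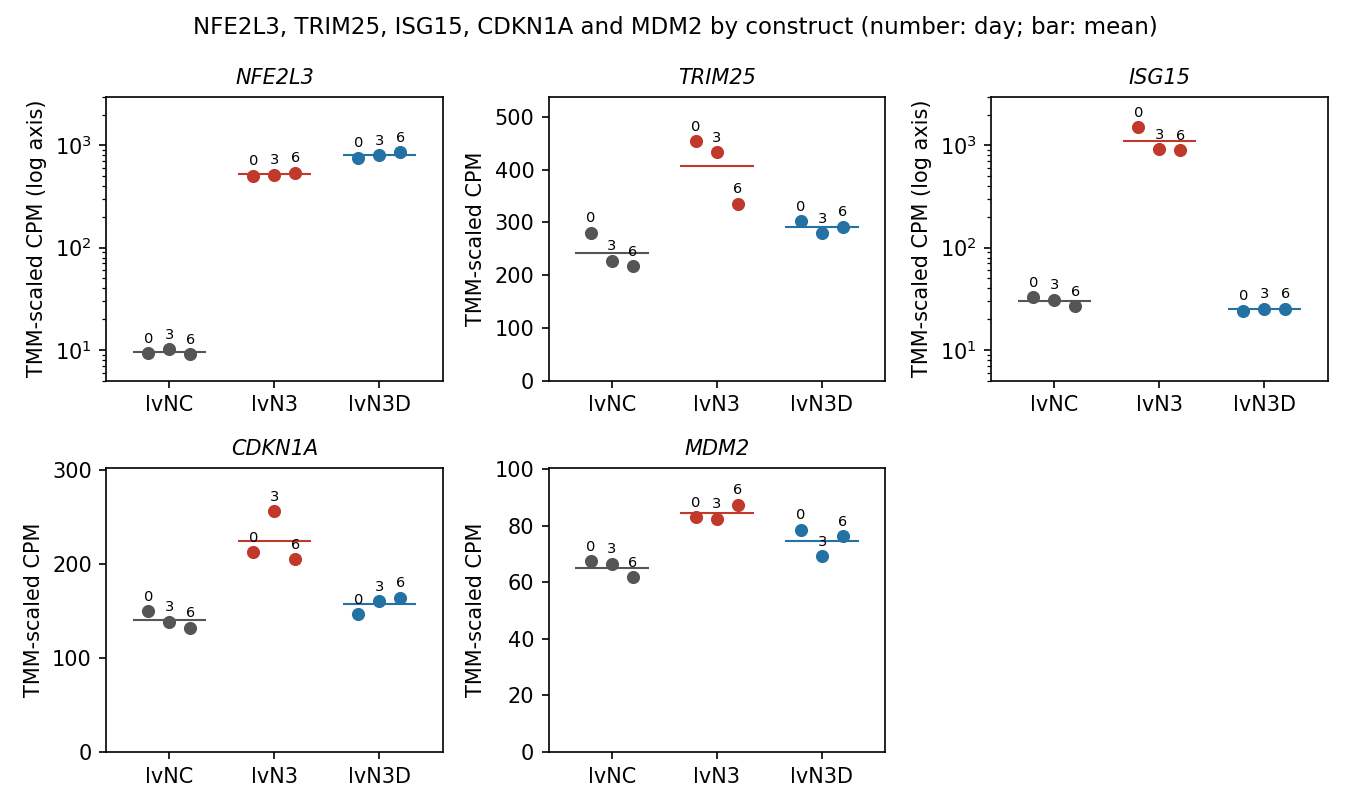
CPM after TMM scaling (y axis, log scale for NFE2L3 and ISG15) of NFE2L3, TRIM25, ISG15, CDKN1A and MDM2 by construct, with a number for the day of each library and a bar for the mean of 3. NFE2L3 was high in both NFE2L3 constructs, and ISG15 was high in lvN3 (mean 1105) but not in lvN3D (24.9).

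The comparison of lvN3 with lvNC asked which genes differed in cells carrying full-length NFE2L3. All 44 interferon-stimulated genes rose, with the largest median change of the 20 lists (4.70), as did all 18 heat shock, 32 of 37 proteasome and 30 of 35 mitosis genes. Of 29 genes of the unfolded protein and integrated stress response 18 fell and 10 rose. None of the 20 lists passed with an estimated correlation, and the smallest was adjusted p = 0.0577 with an estimated correlation, for heat shock. IFI44L, induced by interferon, had 0 counts in the 3 lvNC libraries and 193 ± 61.2 CPM in lvN3, at least 2678-fold higher against a floor of 3 counts over the group. FGF21, a hormone secreted in nutrient stress, fell from 125 to 1.81 CPM (-6.11 ± 0.13, adjusted p = 1.21e-24), a 69.2-fold decrease. Of 16001 genes tested, 10201 (63.8%) passed, 5121 higher and 5080 lower in lvN3, and 2836 of them changed more than 2-fold, 1066 higher and 1770 lower. The median absolute log2 fold change of the calls was 0.62. The split into higher and lower depended on the scaling. On column totals without TMM, an alternative added after seeing the data, the median of all genes moved by -0.14 and the split became 3922 higher and 6403 lower. Limma on FPKM gave 3511 and 5275.

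Among the genes named by the fixed rule, the antiviral gene RSAD2 had 3 counts over the lvNC libraries and 3554 over those of lvN3, a ratio of 1104 (95% interval 377 to 5355). The peptide transporter SLC15A3 had 3 and 2238 (ratio 695, 238 to 3373), and the guanylate-binding protein GBP1 had 1 and 609 (ratio 567, 101 to 22449.9). The noncoding RNA LINC01285 had 0 and 354, at least 110.0-fold higher. These intervals and floors cover counting error only. The interferon-induced genes OAS2 (9.98 ± 0.19), XAF1 (9.42 ± 0.19) and IFI44 (9.39 ± 0.13) had the next largest log2 fold changes. IFI6 rose from 3.89 to 1296 CPM (8.35 ± 0.12, adjusted p = 2.02e-28) and IFI27 from 2.15 to 497 CPM (7.83 ± 0.12, adjusted p = 1.05e-27). Beside FGF21, genes with large decreases were RBBP8NL (-5.59), the inositol oxygenase MIOX (-4.81) and the splicing regulator ESRP1 (-4.74). They were followed by the inhibin subunit INHBE (-4.54 ± 0.07, from 193 to 8.30 CPM), KRT4 (-4.42), TNFRSF9 (-4.42), CHAC1, which degrades glutathione (-4.35 ± 0.09, from 114 to 5.58 CPM), and GDAP1L1 (-4.15). None of these calls was lost when any 1 library was left out.

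All 44 tested genes of the list of interferon-stimulated genes and ISG15 conjugation rose in lvN3, and all 44 passed when adjusted over the list alone, while limma on FPKM called 41. Their median log2 fold change was 4.70, unchanged with 1 member set to its bound, and IFI44, IFI6, IFI27 and IFIT3 (5.95) had the smallest p. The list passed camera at adjusted p = 2.81e-30, and at adjusted p = 0.175 with an estimated correlation it did not. All 18 heat shock genes rose, also when adjusted over the list alone, with a median of 1.38 (camera adjusted p = 5.72e-16; adjusted p = 0.0577 with an estimated correlation). Among these chaperones, HSP90AA1 rose from 725 to 4357 CPM (2.59), HSPA1A by 3.49, HSPA8 by 2.23 and HSPH1 by 1.74 on the log2 scale; HSPA1A shares reads with its near-identical copy HSPA1B, so the pair cannot be separated. Of 37 proteasome genes 32 rose, 1 fell and 4 did not pass, and adjusted over the list alone 32 rose and 1 fell. Their median was 0.58 (camera adjusted p = 4.31e-11; adjusted p = 0.175 with an estimated correlation), with PSMD3 at 1.78, PSMD1 at 1.68, PSMA4 at 1.28 and PSMC6 at 1.24. On column totals 29 rose and 5 fell.

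Of 35 mitosis and G2/M genes 30 rose, 3 fell and 2 did not pass, with the same counts of 30 and 3 adjusted over the list alone and a median of 0.69 (camera adjusted p = 3.98e-11; adjusted p = 0.175 with an estimated correlation). The cyclin CCNB1 (1.94), the kinase AURKA (1.36), KIF20A (1.32) and ANLN (1.12) were among them. Of 32 DNA replication and G1/S genes 22 rose, 6 fell and 4 did not pass, with 22 and 6 adjusted over the list alone (camera adjusted p = 0.00729; adjusted p = 0.712 with an estimated correlation). On column totals 13 rose and 9 fell, and the median of 0.24 became 0.10. GMNN (1.247), RRM2 (1.12) and ORC1 (1.06) rose, and the helicase subunit MCM2 fell (-0.55). Of 27 antioxidant targets of NFE2L2 23 rose, 2 fell and 2 did not pass, with 23 and 2 adjusted over the list alone and a median of 0.54 (camera adjusted p = 5.05e-06; adjusted p = 0.175 with an estimated correlation). PIR (1.75), the glutathione synthesis gene GCLM (1.37) and the transporter ABCC2 (0.90) rose, and the cystine transporter SLC7A11 fell (-1.30). On column totals 18 rose and 4 fell.

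Of 25 cholesterol synthesis genes 16 rose, 1 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 5.05e-06; adjusted p = 0.469 with an estimated correlation). SQLE (1.54), HMGCS1 (1.48), FDFT1 (1.31) and NSDHL (1.26), all enzymes of the pathway, had the smallest p. Of 31 hypoxia and glycolysis genes 25 rose, 4 fell and 2 did not pass, with 25 and 4 adjusted over the list alone (camera adjusted p = 2.54e-06; adjusted p = 0.666 with an estimated correlation). The glycolytic genes HK1 (2.02), LDHA (1.248) and PGAM1 (0.97) rose, and the angiogenic factor VEGFA fell (-1.07). Of 29 genes of the unfolded protein and integrated stress response 18 fell, 10 rose and 1 did not pass, also adjusted over the list alone, with a median of -0.84 (camera adjusted p = 0.00134; adjusted p = 0.289 with an estimated correlation). TRIB3 (-2.32), PPP1R15A (-2.22), and the serine synthesis gene PSAT1 (-1.78) fell with CHAC1.

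The 11 other lists did not pass camera. Of 34 p53 target genes 16 rose and 11 fell (16 and 12 adjusted over the list alone; camera adjusted p = 0.504). On column totals 14 rose and 13 fell, and the median of 0.15 became 0.01. Of these targets SESN2 (-2.04), GDF15 (-1.70) and GADD45A (-1.60) fell, and TRIM22 rose (6.95), which is also induced by interferon. Of 50 ribosomal protein genes 14 rose and 25 fell (14 and 26 adjusted over the list alone; camera adjusted p = 0.0961), with RPS3A (-0.69), RPLP1 (-0.62), RPL5 (-0.57) and RPL13A (-0.53), and on column totals 10 rose and 33 fell. Of 12 mitochondrially encoded genes 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0601), with MT-ND1 at 0.64, MT-ND2 at 0.52, MT-CYB at 0.46 and MT-ND3 at 0.36. On column totals 4 of them rose and 2 fell, and limma on FPKM called 5. Of 35 respiratory chain genes 17 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.291), with ATP5F1B at 0.59, COX5A at 0.57, SDHB at 0.53 and NDUFA4 at 0.50; on column totals 9 rose and 11 fell and the median of 0.10 turned to -0.04. Of 18 fatty acid synthesis and storage genes 8 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.963). ACLY rose (0.56), and MLXIPL (-3.25), FADS1 (-0.82) and FADS2 (-0.78) fell. The median of 0.05 was positive and the mean of -0.13 and the test were negative, and on column totals 6 rose and 8 fell and the median turned to -0.09. Of 18 epithelial-mesenchymal and matrix genes 8 rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.417), with TGFBI at 1.96, VIM at 1.00 and ITGB1 at 0.63.

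Of 9 inflammatory and acute phase genes 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.868). CCL2 (2.28) and NFKBIA (0.51) rose, LCN2 (-1.61) and SOCS3 (-1.253) fell. The median of -0.32 and the mean of 0.24 differed in sign. Of the 7 tested hepatocyte genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.963). The complement gene C3 (2.63) and VTN (1.50) rose, ASGR1 (-1.68; adjusted p = 0.0717 without lvN3 day 3) and CPS1 (-0.28) fell, and the median of -0.28 and the test were negative while the mean of 0.04 was not. Of 8 genes of the CNC-bZIP family and its partners, NFE2L3 among them, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.963). KEAP1, the adaptor that targets NFE2L2 for degradation, rose (0.48), MAFF (-0.57) and BACH1 (-0.35) fell, and the median of -0.13 and the test were negative while the mean of 0.60, which includes NFE2L3, was not. On column totals 2 rose and 6 fell and the median was -0.27. Of 8 markers of stromal, endothelial and blood cells 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.963), namely PECAM1 (2.64), COL3A1 (1.097) and COL1A1 (-0.84). On column totals 2 rose and 3 fell and the median was 0.06. The median of 0.20 and the mean of 0.37 were positive and the test negative. Of 7 cholangiocyte and progenitor markers 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.556). KRT7 (0.75) and CD24 (0.62) rose and SOX4 (-1.22) and PROM1 (-2.29) fell, and the mean of -0.19 differed in sign from the median of 0.16 and the test. On column totals 3 rose and 2 fell and the median was 0.02.

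**Figure D4:**
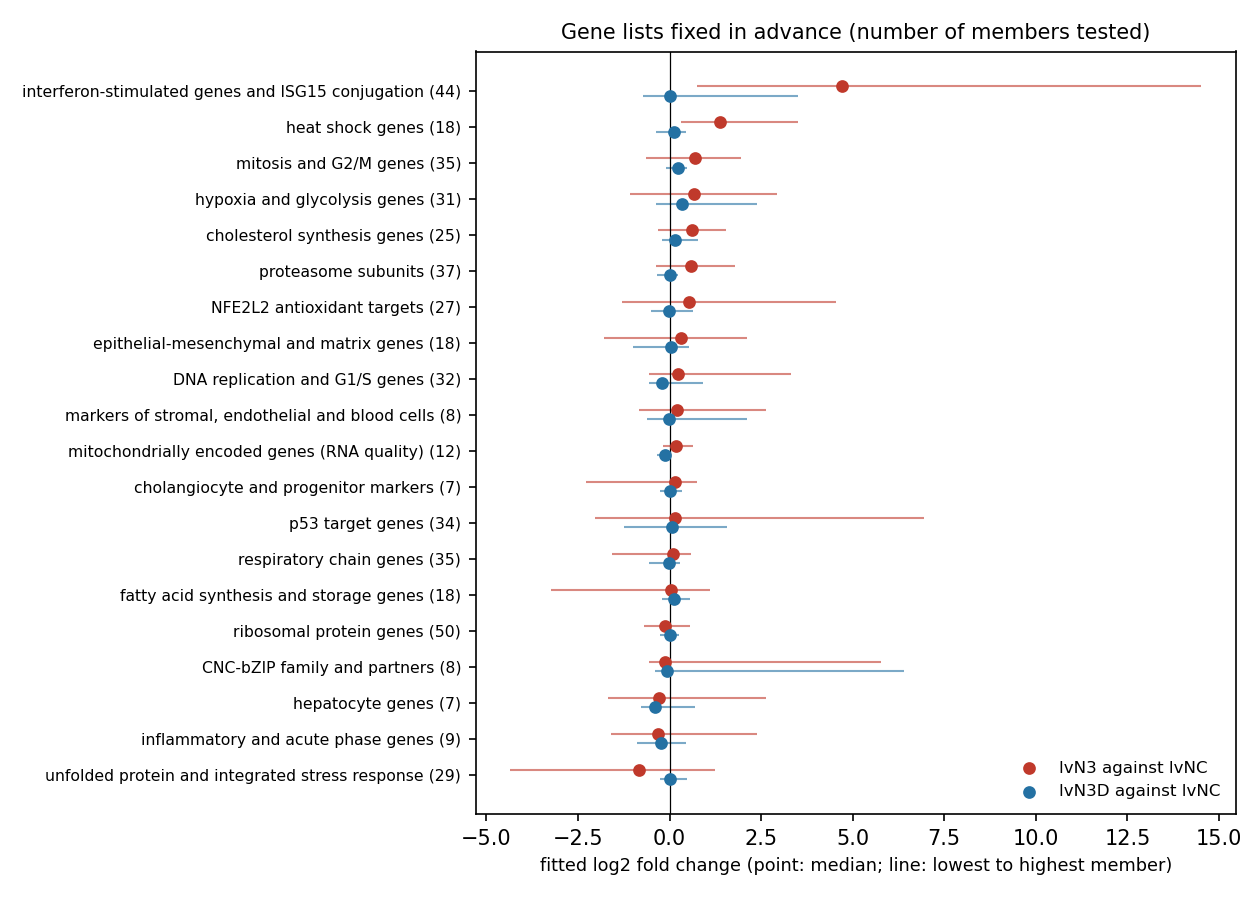
Median log2 fold change (points) of the tested members of the 20 gene lists in lvN3 and lvN3D against lvNC, with lines from the lowest to the highest member (x axis, fitted log2 fold change). The interferon list had a median of 4.70 in lvN3 and 0.01 in lvN3D; its highest member, IFI44L, had 0 counts in lvNC, so that its fitted value depends on the prior count.

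The comparison of lvN3D with lvNC asked the same of NFE2L3 without a part of its C-terminal region. Fewer genes passed than in lvN3 and their changes were smaller. Of the fixed lists, 21 of 31 hypoxia and 23 of 35 mitosis genes rose and 15 of 32 DNA replication genes fell. None of the 20 lists passed with an estimated correlation, and the smallest was adjusted p = 0.170 with an estimated correlation. The carbonic anhydrase CA9 rose from 2.33 to 11.9 CPM (2.39 ± 0.28, adjusted p = 1.69e-06). The mitochondrial subunit NDUFA4L2 rose from 11.1 to 50.3 CPM (2.23 ± 0.20, adjusted p = 2.1e-08) and the oxygen sensor EGLN3 by 1.45 ± 0.15 on the log2 scale (adjusted p = 2.37e-07). Of 16001 genes 1261 (7.88%) passed, 577 higher and 684 lower, 73 of them by more than 2-fold (35 higher and 38 lower), and the median absolute log2 fold change of the calls was 0.30. On column totals 501 were higher and 806 lower. The count was 804 without lvNC day 0, 692 without lvNC day 6, 649 without lvN3D day 0 and 739 without lvN3D day 6, and was 796 with DESeq2 and 530 with limma on FPKM.

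Other genes with large increases were PPFIA4 (1.92), MIR210HG (1.32), the host of a hypoxia-induced microRNA, BAIAP3 (1.27), ALOX12B (1.17) and the chemokine CCL5 (2.30). CCL5 had 3 counts in each lvNC library and 5, 33 and 8 in lvN3D, and its call was lost without lvNC day 0 (adjusted p = 0.0829), lvNC day 3 (0.118) or lvN3D day 3 (0.432), the library with blood-cell marker transcripts, and with limma on FPKM (0.341). Its log2 fold change was 0.99 without lvN3D day 3. The largest decreases were those of the receptor GPR3 (-1.79 ± 0.31, adjusted p = 0.000377), EPB41L3 (-1.36) and the NF-kappa-B subunit RELB (-1.36 ± 0.24, adjusted p = 0.000425). The hormone subunit CGA (-1.30 ± 0.20, adjusted p = 9.62e-05), the cytokine IL11 (-1.28 ± 0.18, from 11.1 to 4.50 CPM) and RYR2 (-1.23) followed. ZNF488 (-1.65), ZNF208 (-1.38), HRASLS2 (-1.31) and TMEM132B (-1.104) also passed. Without 1 library the call was lost for ZNF488 (0.0702 without lvN3D day 6), ZNF208 (0.0874 without lvNC day 3 and 0.0586 without lvN3D day 3), HRASLS2 (0.0964 without lvNC day 6 and 0.0619 without lvN3D day 6, and 0.0726 with limma on FPKM) and TMEM132B (0.0538 without lvNC day 3).

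Of 31 hypoxia and glycolysis genes 21 rose, 1 fell and 9 did not pass in lvN3D, and 24 rose and 1 fell adjusted over the list alone. Their median was 0.33 (camera adjusted p = 1.09e-26; adjusted p = 0.176 with an estimated correlation), and NDRG1 (1.08) and LDHA (0.56) rose with EGLN3 and CA9. Of 35 mitosis and G2/M genes 23 rose and 12 did not pass (25 rose adjusted over the list alone; camera adjusted p = 1.14e-17; adjusted p = 0.170 with an estimated correlation), with CENPE (0.49), KIF20A (0.44), PLK1 (0.41) and ANLN (0.31). Of 32 DNA replication and G1/S genes 15 fell and 17 did not pass (23 fell adjusted over the list alone; camera adjusted p = 1.47e-16; adjusted p = 0.176 with an estimated correlation), with CDC45 (-0.57), UHRF1 (-0.45), CDC25A (-0.42) and E2F2 (-0.41). Of 18 heat shock genes 5 rose and 13 did not pass (11 rose adjusted over the list alone; camera adjusted p = 2.26e-07; adjusted p = 0.170 with an estimated correlation), with HSPA8 (0.45), HSPA1A (0.36, shared with HSPA1B), HSP90AA1 (0.24) and HSPD1 (0.22). Of 25 cholesterol synthesis genes 8 rose and 17 did not pass (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.19e-06; adjusted p = 0.517 with an estimated correlation), with INSIG1 (0.77), STARD4 (0.45) and FDFT1 (0.44). Of 18 fatty acid synthesis and storage genes 4 rose and 14 did not pass (7 rose adjusted over the list alone; camera adjusted p = 6.57e-06; adjusted p = 0.176 with an estimated correlation), with SCD (0.55), LPIN1 (0.40), SREBF1 (0.30) and FASN (0.25). Of 12 mitochondrially encoded genes 5 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 1.62e-05; adjusted p = 0.582 with an estimated correlation), with MT-ND6 at -0.33. The list's call was lost without lvN3D day 6 (adjusted p = 0.222). With fry, which tests whether the genes of a list move one way, the hypoxia (adjusted p = 0.0522), cholesterol (0.107) and mitochondrial lists (0.470) did not pass. Limma on FPKM called 12 hypoxia and 13 mitosis genes and not FASN (adjusted p = 0.0534), and DESeq2 and limma on FPKM each called 1 mitochondrially encoded gene.

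The interferon list did not pass in lvN3D. Of its 44 genes TRIM25 rose, OAS3 fell (-0.31, adjusted p = 0.016) and 42 did not pass, also adjusted over the list alone, with a median of 0.01 and camera adjusted p = 0.870. Without lvNC day 3, lvNC day 6, lvN3D day 0 or lvN3D day 3, the OAS3 call was lost (adjusted p = 0.0682, 0.208, 0.182 and 0.0901), and it was lost with DESeq2 (0.253) and limma on FPKM (0.184), which called none of the 44. With DESeq2's size factors in edgeR 2 of the list rose and 1 fell. None of 37 proteasome genes passed, over all genes or adjusted over the list alone (8 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma on FPKM; camera adjusted p = 0.792), and on column totals 2 fell. Of 34 p53 target genes 2 rose and 3 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.541), among them RPS27L (0.36; adjusted p = 0.0520 with limma on FPKM) and GADD45A (-0.45), and with DESeq2's size factors 5 rose and 3 fell. Of 27 NFE2L2 targets 1 rose and 5 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.460). Of 29 genes of the unfolded protein and integrated stress response 4 rose, the chaperone HSP90B1 (0.39) among them, and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.171).

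Of 8 CNC-bZIP genes NFE2L3 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.852), among them MAFK (-0.34) and MAFG (-0.28). The median of -0.06 differed in sign from the mean of 0.68 and the test. Of 18 epithelial-mesenchymal and matrix genes 2 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.879). On column totals 1 rose and 3 fell. The matricellular genes CYR61 (-1.001) and CTGF (-1.002) fell, and the median of 0.05 differed in sign from the mean of -0.04 and the test. Of 9 inflammatory genes 1 rose and 1 fell, SOCS3 (-0.37) (2 and 3 adjusted over the list alone; camera adjusted p = 0.392). Of 50 ribosomal protein genes 1 rose, RPL4 (0.27), and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.852). Of 35 respiratory chain genes 6 fell (1 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.542). SDHD was among them (-0.28), a call lost without lvNC day 0 (0.0530), lvNC day 6 (0.0607) or lvN3D day 0 (0.0631). Of 7 hepatocyte genes CPS1 rose (0.24) and 1 fell, also adjusted over the list alone (camera adjusted p = 0.906), and the median of -0.40 and the mean of -0.20 were negative and the test positive. None of 7 cholangiocyte markers passed, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma on FPKM; camera adjusted p = 0.852). The median and the mean, both 0.02, were positive and the test negative. Of 8 stromal, endothelial and blood markers PECAM1 passed (2.10, adjusted p = 0.0436), and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.964; the median of -0.01 and the test were negative and the mean of 0.19 was not). The PECAM1 call was lost without lvNC day 3 (0.357), lvNC day 6 (0.117), lvN3 day 0 (0.0525) or lvN3D day 3 (0.763), the library with blood-cell marker transcripts. Its log2 fold change was 0.49 without lvN3D day 3 and 1.39 without lvNC day 3. On column totals 1 of these markers rose and 1 fell. DESeq2 and limma on FPKM called 4 and 1 stress response genes, 4 and 2 p53 targets, 3 and 1 respiratory chain genes and 2 and 1 ribosomal protein genes in lvN3D.

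The direct comparison of lvN3 with lvN3D asked how the constructs with and without the C-terminal part differed. Interferon-induced genes led the increases: IFI44L (10.99 ± 0.18), OAS2 (9.78), XAF1 (9.43), IFI44 (8.69), RSAD2 (8.47), IFI6 (8.42), IFITM1 (8.10, one of a family of near-identical genes that share reads) and IFI27 (7.95). The tryptophan-degrading enzyme KYNU rose by 7.20 ± 0.17, and the arrestin gene SAG had 0 counts in lvN3D and 255 in lvN3, at least 80.1-fold higher. Genes with large decreases were FGF21 (-6.02 ± 0.13), RBBP8NL (-4.95), MIOX (-4.62), INHBE (-4.60), GAGE12J (-4.57, one of a family of near-identical copies), CHAC1 (-4.50), GALNTL6 (-4.29), ESRP1 (-4.28) and TNFRSF9 (-4.22). Of 16001 genes 10123 (63.3%) passed, 5166 higher and 4957 lower in lvN3, and 2713 changed more than 2-fold (1044 higher and 1669 lower). On column totals the median of all genes moved by -0.12 and the split became 4075 higher and 6215 lower.

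All 44 interferon-stimulated genes were higher in lvN3 than in lvN3D, also adjusted over the list alone (camera adjusted p = 1.67e-30; adjusted p = 0.221 with an estimated correlation). So were all 18 heat shock genes (2.31e-15; adjusted p = 0.0634 with an estimated correlation) and all 12 mitochondrially encoded genes (0.000765; adjusted p = 0.598 with an estimated correlation). On column totals 17 of the 18 and 7 of the 12 were higher, DESeq2 called 8 of the 12, and limma on FPKM called 41, 17 and 5 genes of these 3 lists. Of 37 proteasome genes 32 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 7.16e-12; adjusted p = 0.221 with an estimated correlation), with PSMD3 (1.74), PSMD1 (1.59), PSMD2 (1.12) and PSMD11 (1.06). Of 32 DNA replication genes 26 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 4.68e-07; adjusted p = 0.383 with an estimated correlation), with RRM2 (1.43), GMNN (1.253), ORC1 (1.17) and MCM5 (0.78). Of 35 mitosis genes 27 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 4.68e-07; adjusted p = 0.249 with an estimated correlation), with CCNB1 (1.58) and AURKB (1.03). Of 27 NFE2L2 targets 22 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 4.04e-06; adjusted p = 0.221 with an estimated correlation), with OSGIN1 (2.53), PIR (2.22), GCLM (1.67) and TALDO1 (1.00). Of 29 stress response genes 18 were lower and 10 higher, also adjusted over the list alone (camera adjusted p = 0.000765; adjusted p = 0.249 with an estimated correlation). Of 25 cholesterol synthesis genes 15 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.000901; adjusted p = 0.598 with an estimated correlation), and on column totals 12 were higher and 4 lower. Of 31 hypoxia and glycolysis genes 16 were higher and 7 lower (17 and 7 adjusted over the list alone; camera adjusted p = 0.0479; adjusted p = 0.792 with an estimated correlation). That call was lost without lvN3 day 0 (0.0604), lvN3 day 3 (0.243), lvN3D day 0 (0.0850) or lvN3D day 3 (0.11) and with fry (0.0669). The other 10 lists did not pass, with camera adjusted p between 0.0918 and 0.912, and the signs of median, mean and test differed for the hepatocyte, inflammatory, stromal and cholangiocyte lists.

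The F test over the 3 constructs called 10823 of 16001 genes (67.6%). Genes called against lvNC in both NFE2L3 constructs were counted by direction to ask how far the responses overlapped. Both were higher for 341 genes and both lower for 319, against 184.7 and 217.2 for independent lists, while 209 rose in lvN3 and fell in lvN3D (218.9 for independent lists) and 125 did the reverse (183.2). The 660 calls of 1 direction became 431 without lvNC day 0, 366 without lvNC day 6, 356 without lvN3D day 0 and 423 without lvN3D day 6. The log2 fold changes of the 2 comparisons had a covariance of 0.0834 across genes. Unchanged groups that shared simulated controls gave 0.0236, a difference of 0.0598. The correlation across genes was 0.258 against 0.501 in the simulation, and the share of genes with the same sign was 56.8% against 66.6%. In the 20 simulations no gene was called in both comparisons in the same direction. As they were drawn without any effect, that count is no test of the overlap. The simulated correlation and share of signs came from the shared controls alone, and changes confined to lvN3 can lower both. The lower real values are thus no sign of an overlap below chance. The 3 controls cannot be divided into parts of at least 2 libraries, so part of the excess may come from the shared controls.

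Across constructs, few genes differed between days. Day 6 against day 0 had 26 calls, 5 higher and 21 lower, and 15 of them were interferon-stimulated genes of the fixed list. The direction of the calls rested on lvN3 day 6, since without it 18 genes were called, 16 higher and 2 lower, and 4 of them were shared with the 26. The lysyl oxidase gene LOXL2 (0.40 ± 0.07, adjusted p = 0.0122), the growth factor-binding protein IGFBP3 (0.38 ± 0.06, adjusted p = 0.00114) and NDUFA4L2 (0.91 ± 0.19, adjusted p = 0.0377) rose, as did GPR161 (0.37, adjusted p = 0.0287) and IGFL2-AS1 (0.27, adjusted p = 0.027). The last is an antisense gene, and the strand setting of the counting is not given in the sources used here. The 8 genes with a lower value at day 6 in all constructs were RSAD2 (-1.18 ± 0.15, adjusted p = 5.39e-05), SLC15A3 (-1.13), IFIT3 (-0.95 ± 0.10, adjusted p = 2.39e-06) and the RNA sensors DDX58 (-0.87) and IFIH1 (-0.75), and SP100 (-0.42), PARP9 (-0.42) and the splicing factor SRSF3 (-0.25, adjusted p = 0.0476). RSAD2 and SLC15A3 had 3 counts each over the lvNC libraries, so their sign in lvNC rested on at most 3 reads. The median change per gene of the 44 interferon-stimulated genes was -0.0045 from day 0 to day 3 and -0.019 from day 3 to day 6 in lvNC. It was -0.36 and -0.36 in lvN3, and 0.11 and 0.0008 in lvN3D. The count of 26 calls became 0 without lvN3 day 0, 54 without lvNC day 0 and 41 without lvN3D day 0, and 1 with DESeq2 and 0 with limma on FPKM. Without lvN3 day 0 the adjusted p of the 13 genes named here was between 0.0514 (SRSF3) and 0.991 (SLC15A3). The log2 fold change was then -0.71 for RSAD2, -0.32 for SLC15A3, -0.55 for IFIT3 and -0.59 for DDX58. It was -0.46 for IFIH1, -0.43 for SP100, -0.15 for PARP9 and -0.35 for SRSF3. RSAD2 was at -4.96 without lvN3 day 6. Without lvN3 day 6 the call was lost for GPR161 (0.0578), IGFL2-AS1 (0.155), RSAD2 (0.300), SLC15A3 (0.848), IFIT3 (0.155), DDX58 (0.887), IFIH1 (0.860), SP100 (0.534) and PARP9 (0.847). Leaving out an lvNC library ended the call of NDUFA4L2 (0.139), LOXL2 (0.0857) and GPR161 (0.157) for day 6, of PARP9 (0.0890) for day 3, and of SRSF3 for day 0 (0.203), day 3 (0.108) or day 6 (0.529). Leaving out an lvN3D library ended that of GPR161 (0.363), IGFL2-AS1 (0.0953) and SRSF3 (0.326) for day 0, of PARP9 (0.0685) and SRSF3 (0.0837) for day 3, and of NDUFA4L2 (0.348), LOXL2 (0.168), GPR161 (0.168), IGFL2-AS1 (0.248) and SRSF3 (0.278) for day 6.

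Day 3 against day 0 had 0 calls with edgeR (708 genes at an unadjusted p under 0.05, where chance gives 800), with 1 by DESeq2 and 0 by limma on FPKM. It had 2 without lvNC day 0 or lvN3 day 6, 4 without lvN3 day 3 and 1 without lvN3 day 0, lvN3D day 0 or lvN3D day 6. Day 6 against day 3 had 1 call, IFIT3 (-0.57, adjusted p = 0.0466), chosen after its values were seen, with 0 calls by DESeq2 and by limma on FPKM. It had 0 without lvNC day 3 or lvN3D day 3, 2 without lvNC day 0, lvNC day 6 or lvN3D day 6, and 8 without lvN3 day 3, of which 3 were higher and 5 lower. Without lvN3 day 6 the 1 call was higher, and IFIT3 was called in neither of these fits. The F test over the days called 17 genes, 11 of them in the interferon list, and it called 33 without lvNC day 0, 11 without lvNC day 3, 8 without lvN3 day 0, 35 without lvN3 day 3 and 27 without lvN3D day 0.

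Of the 44 interferon-stimulated genes 15 fell from day 0 to day 6 and 29 did not pass, and 35 fell adjusted over the list alone. Camera gave adjusted p = 1.06e-104, adjusted p = 0.0794 with an estimated correlation, and 0.370 without lvN3 day 0. With fry it was 0.135, and no list passed fry between days. From day 0 to day 3 none passed over all genes (19 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma on FPKM), and 12 were lower adjusted over the list alone (camera adjusted p = 2.02e-44; adjusted p = 0.386 with an estimated correlation). Without lvN3 day 0 the list turned to higher (2.87e-07). That fit had no lvN3 library at day 0. Per gene, the median change from day 0 to day 3 was -0.36 in lvN3, -0.0045 in lvNC and 0.11 in lvN3D. From day 3 to day 6, 1 fell and 18 were lower adjusted over the list alone (camera adjusted p = 4.27e-45; adjusted p = 0.457 with an estimated correlation). Without lvN3 day 6 the list turned to higher (0.0145). That fit had no lvN3 library at day 6. Per gene, the median change from day 3 to day 6 was -0.36 in lvN3, -0.019 in lvNC and 0.0008 in lvN3D. The hypoxia list was higher at day 6 than at day 0 (camera adjusted p = 2.11e-13; adjusted p = 0.693 with an estimated correlation). Of its genes 9 passed adjusted over the list alone and none over all genes (12 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma on FPKM). NDRG1 was at 0.36, PFKFB4 at 0.50, CA9 at 0.87 and EGLN3 at 0.50. Without lvN3 day 6 these genes passed (adjusted p = 0.000789, 0.00646, 0.000816 and 0.00181 in that order), and without lvN3 day 3 NDRG1 (0.00024), CA9 (0.0401) and EGLN3 (0.0401) did.

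Other lists that passed camera between days had no gene past the threshold over all genes with edgeR, nor any with limma on FPKM, and DESeq2 called 1 mitochondrially encoded gene from day 0 to day 3. From day 0 to day 6 the NFE2L2 targets (camera adjusted p = 0.00653; adjusted p = 0.693 with an estimated correlation) and the mitochondrially encoded genes (1.86e-05; adjusted p = 0.715) were lower. The first call was lost without lvNC day 0 (0.196) or lvNC day 6 (0.427), and the second turned in direction without lvN3D day 0 (0.659) or lvN3D day 6 (0.757). From day 0 to day 3 the NFE2L2 targets (0.000647), cholesterol synthesis (5.41e-08), heat shock (0.0382), ribosomal protein (5.96e-10) and mitochondrially encoded genes (5.94e-08) were lower and the CNC-bZIP (0.0382) and hypoxia genes (4.01e-09) higher. The smallest of these adjusted p was 0.386 with an estimated correlation. Without lvN3 day 3 the calls were lost for the NFE2L2 (0.190), cholesterol (0.302), CNC-bZIP (0.513), hypoxia (0.946), heat shock (0.325) and mitochondrially encoded genes (0.119). Without lvNC day 0 they were lost for the NFE2L2 (0.10) and heat shock genes (0.341), and the ribosomal protein genes turned in direction (0.699). The CNC-bZIP call was also lost without lvN3 day 0 (0.142), lvN3D day 0 (0.262) or lvN3D day 3 (0.0630) and the heat shock call without lvNC day 3 (0.128), lvNC day 6 (0.0552) or lvN3 day 0 (0.174). The mitochondrial call was lost without lvN3D day 0 (0.854). From day 3 to day 6 the p53 targets were lower (0.0102; adjusted p = 0.945 with an estimated correlation), and the stress response (0.00071; adjusted p = 0.833), cholesterol (0.00982; adjusted p = 0.945) and ribosomal protein genes (1.36e-07; adjusted p = 0.945) higher. Without lvN3 day 3 the p53 (0.547) and stress response calls (0.575) were lost and the cholesterol genes turned (0.575), and the same held without lvN3 day 6 (0.0505, 0.183 and 0.634). The p53 call was also lost without lvNC day 6 (0.351), and the ribosomal call without lvN3D day 6 (0.290). Adjusted over the list alone, 1 mitochondrially encoded gene was lower from day 0 to day 3, 2 stress response genes were higher from day 3 to day 6, and no gene of the other lists named here passed. The signs of median, mean and test differed for the cholangiocyte and DNA replication lists from day 0 to day 3, the inflammatory list from day 0 to day 6, and the mitosis, NFE2L2, DNA replication and respiratory chain lists from day 3 to day 6, none of which passed.

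**Figure D5:**
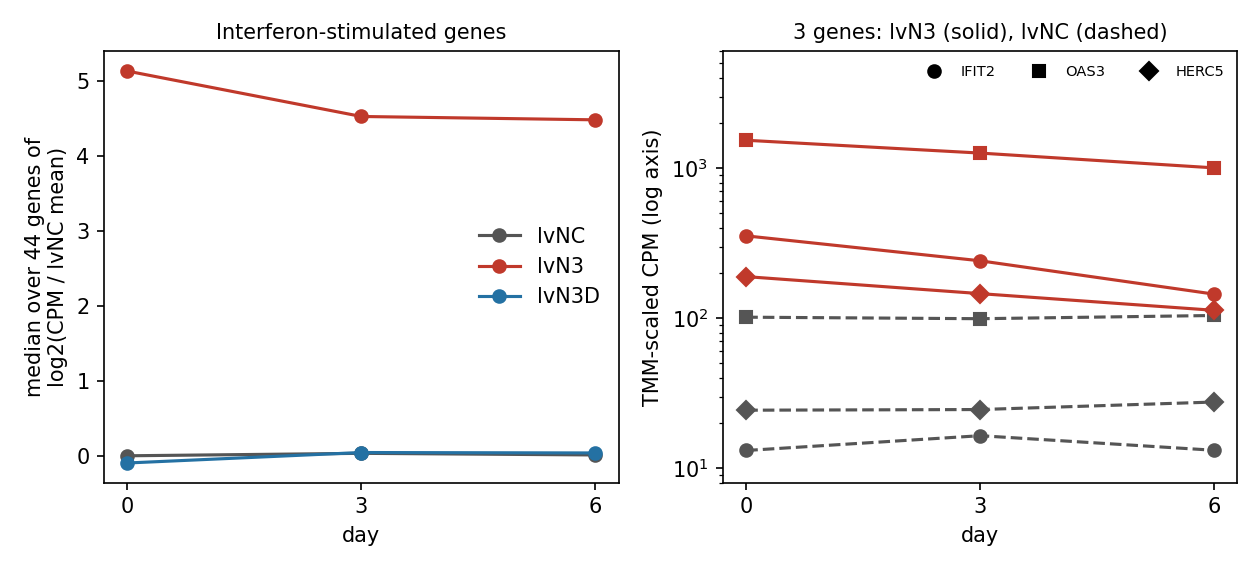
Left, median over 44 interferon-stimulated genes of log2(CPM / lvNC mean) by day for the 3 constructs; right, CPM after TMM scaling (log axis) of IFIT2, OAS3 and HERC5 by day in lvN3 (solid lines) and lvNC (dashed lines), genes chosen after their values were seen. The lvN3 median went from 5.14 at day 0 to 4.53 and 4.49, and the lvN3D values stayed between -0.10 and 0.04.

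Whether the change over days differed between constructs was tested with the interaction of construct and day. In lvN3 against lvNC 12 genes had a lower slope and none a higher one, and 7 of them were in the interferon list. The RNA-binding IFIT2 changed by -0.21 log2 per day relative to lvNC (adjusted p = 0.0111), being at 354, 241 and 145 CPM at days 0, 3 and 6 in lvN3 and at 13.1, 16.4 and 13.1 in lvNC. Without lvNC day 0 its slope difference was -0.105. The antiviral synthetase OAS3 (-0.11, adjusted p = 0.0139) was at 1535, 1261 and 1005 CPM in lvN3. HERC5, a ligase of ISG15, had a slope of -0.15 (adjusted p = 0.0227); these 3 genes were chosen after their values were seen. Leaving out 1 library besides lvNC day 0 ended the IFIT2 call for lvN3 day 6 (0.0995) and the HERC5 call for lvNC day 3 (0.0507). The OAS3 and HERC5 calls ended without lvNC day 6 (0.765 and 0.869), lvN3 day 0 (0.0635 and 0.178) or lvN3 day 6 (0.279 and 0.251). With DESeq2 the IFIT2 (0.440) and HERC5 (0.136) calls were lost. The count of 12 became 0 without lvNC day 0, 4 without lvNC day 6 or lvN3 day 6, 29 without lvN3 day 0 or lvN3D day 6, 24 without lvN3 day 3 and 37 without lvN3D day 0 or lvN3D day 3, and was 3 with DESeq2. Without lvN3 day 0, 10 of the 29 slopes were higher and 5 of the 12 were still called, and 2 and 1 of the 12 were without lvNC day 6 and lvN3 day 6. In lvN3D against lvNC no slope differed with edgeR (1118 genes at an unadjusted p under 0.05) or DESeq2. The count was 1, 2 and 3 without lvNC days 0, 3 and 6, 25, 23 and 19 without lvN3 days 0, 3 and 6, and 10, 29 and 10 without lvN3D days 0, 3 and 6.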

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

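The tests of the hepatocyte genes and of the interferon-stimulated genes in lvN3, and the changes per gene between days, were chosen only after those results were seen; the tests of the slopes and the other splits of the libraries were planned.

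In libraries labelled HepG2, 26 of 33 hepatocyte genes were under 1 CPM in every library. Depth argues against too few reads, since 12673 genes reached 1 CPM in every library. KRT7 at 1299.89 CPM and COL1A1 at 154 CPM were high in the same libraries, but KRT19 (0.00751), EPCAM (0.0156), COL1A2 (0.0439), PDGFRA (0.0292) and LUM (0.547) were low, so they name no other cell type. Whether these genes were lost in counting, or these cells are of another origin than the label or lost hepatocyte expression in culture, cannot be told apart, because the count of 26 is the pattern itself, all libraries have the same label and no reference library of HepG2 was used here.

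All 44 interferon-stimulated genes were higher in lvN3 than in lvNC. A difference in scaling is argued against, since on column totals, which moved the median of all genes by -0.136, their median was 4.57. The amount of NFE2L3 RNA alone is argued against by lvN3D, which had more NFE2L3 than lvN3 (-0.63 for lvN3 against lvN3D) and a list median of 0.0146. A difference between the cultures other than the construct, such as a response to the infection in 1 culture, may also account for it and cannot be told apart, as each construct was sampled from what may be 1 culture. The clustering of changes along chromosomes, 1.83 times the permuted mean in lvN3 against lvNC, 2.42 in lvN3D against lvNC, 2.24 in lvN3 against lvN3D and 1.69 in day 6 against day 0, was above the highest of 200 permutations in each (235 bins of 40 genes), also where no constructs were compared, so it decided nothing, and the biological explanation, the C-terminal part missing in lvN3D, stays untested as a cause.

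Interferon-stimulated genes fell over days in lvN3 relative to lvNC, and 12 slopes, 7 of them of genes in the interferon list, differed by a test of the difference itself. A scaling difference between libraries is argued against by the median slope of the 44 genes, -0.111 log2 per day, below all 10000 random lists of the same size and expression (95% of them between -0.00735 and 0.0116). Without any 1 library the median was between -0.118 and -0.104, which argues against 1 outlying library as the whole source, and the median change per gene in lvN3 was -0.36 from day 0 to day 3 (43 of 44 lower) and -0.36 from day 3 to day 6 (42 of 44). The single calls are less stable, as none passed without lvNC day 0 and 10 of 29 were higher without lvN3 day 0. A change over time in the lvN3 culture remains open as a hypothesis, since there is 1 library per day.

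Slopes among the 12, each a difference between constructs in log2 per day, were -0.21 for IFIT2, -0.38 for APOL6, -0.11 for OAS3, -0.12 for ZNFX1, -0.15 for SLFN5, -0.15 for HERC5, -0.12 for STAT2, -0.13 for OAS1, -0.12 for TXNIP, -0.13 for IFI35 and -0.15 for PML. TXNIP was at 87.8, 93.2 and 72.5 CPM at days 0, 3 and 6 in lvN3. In lvNC it was at 307, 394 and 415 CPM, so its lower slope came in part from a rise in the control. The same held for APOL6, at 35.2, 24.5 and 16.1 CPM in lvN3 and 1.81, 2.95 and 4.18 in lvNC. In lvN3D APOL6 was at 2.23, 2.45 and 1.98 CPM. The APOL6 call was lost without lvNC day 6 (adjusted p = 0.555) or lvN3 day 6 (0.0891), and with DESeq2 (0.0786). Its slope in these fits was -0.43, -0.37 and -0.39. Some slopes moved without 1 library. SLFN5 was at -0.062 without lvNC day 0 and -0.074 without lvN3 day 0. TXNIP was at -0.069 without lvNC day 0 and -0.045 without lvN3 day 6.

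Other splits of the libraries were refitted and their counts of calls compared with the real ones. For 2 constructs or 2 days, 6 libraries make 10 splits, too few for a share under 0.05. For 2 constructs the other splits mix libraries of both, so a construct difference enters their spread. The 0 calls of such splits are thus no support for the calls of the real split. The real split gave 10201 calls and the highest other 0 for lvN3 against lvNC, 1261 and 0 for lvN3D against lvNC, 10123 and 0 for lvN3 against lvN3D, and 12 and 0 for the slopes in lvN3 (1 of 10 splits as large in each). For day 3 against day 0 it was 0 and 3 (10 of 10), for day 6 against day 0 26 and 50 (7 of 10), for day 6 against day 3 1 and 12 (7 of 10). For slopes in lvN3D it was 0 and 766 (10 of 10), and 1 further split gave 611. The split with 766 exchanged the labels of lvNC and lvN3D at days 3 and 6, and that with 611 at day 6 alone. Such an exchange turns a constant construct difference into an apparent slope, so these counts do not point to a further structure of the libraries. Over 100 splits of the 9 libraries, the F test over constructs gave 10823 and the highest other 9322 (1 of 100). The split with 9322 calls, and another with 8950, kept the 3 lvN3 libraries together. The rank thus shows that libraries of a construct resembled each other. It cannot exclude a chance difference between cultures, since each construct may be 1 culture. The F test over days gave 17 and 64 (58 of 100), so chance is not excluded there. The lists past camera were 9 in the real split and 10 in the highest other for lvN3 against lvNC (5 of 10), 7 and 11 for lvN3D against lvNC (8 of 10), and 10 and 10 for lvN3 against lvN3D (2 of 10). They were 8 and 11 for day 3 against day 0 (6 of 10), 4 and 10 for day 6 against day 0 (7 of 10), and 5 and 10 for day 6 against day 3 (8 of 10). The mixed splits of constructs keep part of any construct difference, so their counts of lists are no reference without an effect.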

How the results depend on the processing

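The alternatives on slopes without 1 library, on column totals and on the overlap of responses were chosen after seeing the data; the others were planned. Of 5130 values of named genes, 4724 kept their direction and side of the threshold, 350 lost their call, 54 gained one and 2 reversed; of 473 list values 373 kept both, 93 lost their call and 7 reversed. Without 1 library the counts were 9362 to 10334 for lvN3 against lvNC, 9266 to 10334 for lvN3 against lvN3D and 9881 to 10634 for the F test over constructs.

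For lvN3D against lvNC the 1261 calls became 796 with DESeq2, 530 with limma on FPKM + 1, 496 with FPKM + 0.1, 4 without the FPKM filter, and 649 to 1333 without 1 library. Day 3 against day 0 (0 calls) had 67 without the filter, 1 with DESeq2, 3 with only the 6 libraries and 0 to 4 without 1 library. Day 6 against day 0 (26) had 85 without the filter, 1 with DESeq2, 0 with limma on FPKM + 1, FPKM + 0.1 and FPKM without the filter, 0 without construct as a factor, 17 with only the 6 libraries and 0 to 54 without 1 library. Day 6 against day 3 (1) had 60 without the filter, 0 with DESeq2, the 3 FPKM settings and without construct, and 0 to 8 without 1 library. The F test over days (17) had 137 without the filter, 2 with DESeq2, 0 with the 3 FPKM settings and without construct, and 8 to 35 without 1 library. Slopes in lvN3 (12) had 33 without the filter, 3 with DESeq2 and 0 to 37 without 1 library. Slopes in lvN3D (0) had 2 with DESeq2 size factors, 41 without the filter and 1 to 29. The 660 calls of 1 direction in both constructs became 419 with DESeq2, 298, 277 and 2 with the FPKM settings, and 356 to 680 without 1 library. With an estimated correlation 0 lists passed in each of the 6 comparisons. Fry passed 15 for lvN3 against lvNC (all 9 of camera among them), 5 for lvN3D against lvNC (4 of 7), 14 for lvN3 against lvN3D (9 of 10) and 0 for each pair of days. Without 1 library 2 to 10, 4 to 7 and 3 to 7 lists passed for days 3 and 0, 6 and 0, and 6 and 3. The cause was not tested.

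OAS2 in day 6 against day 0 reversed to 0.41 with DESeq2 and 2.05 without lvN3 day 0, the highest value without 1 library (lowest -1.25). Lists reversed without 1 library, given as camera adjusted p with the range over libraries. For day 3 against day 0 these were the interferon (2.87e-07; 4.44e-70 to 0.00302) and ribosomal lists (0.699; 6.28e-28 to 0.699), and for day 6 against day 0 the mitochondrial list (0.659 and 0.757; 4.39e-17 to 0.757). For day 6 against day 3 they were the interferon (0.0145; 1.28e-60 to 0.0145) and cholesterol lists (0.575 and 0.634; 1.09e-06 to 0.634). The interferon list reversed in fits without lvN3 day 0 or lvN3 day 6, where a compared day had no library of lvN3, the construct in which the list fell. The cause of the other reversals was not tested. Day was a factor of the fits of constructs, which are thus paired by day, and without it the calls were 10239 for lvN3 against lvNC, 1283 for lvN3D against lvNC and 10168 for lvN3 against lvN3D. At the depth of 14017031 to 16077949 counts, 3 counts in 1 library were 0.187 to 0.214 CPM, while the floor of fold bounds was 3 counts over a group.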

Other observations

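The gene sets of this part were chosen after their values were seen.

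Transcripts of interferons themselves were few. The most abundant, IFNE, had 16 counts in lvNC, 34 in lvN3 and 44 in lvN3D, and did not pass edgeR's test in lvN3 (adjusted p = 0.0967) or lvN3D (0.0968). The type I interferon gene IFNB1 had 10, 9 and 8 counts in lvN3 at days 0, 3 and 6, 27 in all, against 2 in lvNC and 1 in lvN3D. The ratio of lvN3 to lvNC was 12.6 (95% interval 3.16 to 109, counting error only). The type III interferon genes had no counts in lvNC or lvN3D. At days 0, 3 and 6 of lvN3, IFNL1 had 0, 7 and 4 counts, IFNL2 had 2, 4 and 0 and IFNL3 had 7, 0 and 0, and the last 2 genes are near-identical copies that share reads. In lvNC, lvN3 and lvN3D, IFNA1 had 1, 4 and 1 counts, IFNA8 had 2, 1 and 3, IFNK had 0, 1 and 2 and IFNW1 had 0, 1 and 0.

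Genes of antigen presentation by class I molecules were higher in lvN3 than in lvNC for 7 of 7 tested with edgeR, among them HLA-B (4.35), HLA-C (3.21), B2M (1.81), the transactivator NLRC5 (1.75), HLA-E (1.40) and the peptide transporter TAP2 (0.94). In lvN3D 4 of the 7 were called. HLA genes share reads with one another, and the lvN3D library of day 3 held blood-cell marker transcripts, which bear on HLA-B, HLA-C and HLA-E (SD 14.2, 16.1 and 20.4 CPM in lvN3D, and 1.81, 0.463 and 4.24 in lvNC).

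In the lvN3D library of day 3, genes outside the fixed marker list also stood apart, namely the granulocyte genes CSF3R (364 counts against 34 in the other 8 libraries together), S100A9 (257 and 5) and FCGR3B (171 and 1), and SERPINA1, listed among hepatocyte genes (53 and 31).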
